A study of Mus musculus with 6 samples.

How the data were processed

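MicroRNA libraries of cultured bone marrow GMLPs were analysed in 2 groups, ME (n = 3) and L28BME (n = 3), in 1 comparison. The groups follow the genotype labels. Per the labels' protocols, total RNA was used and libraries were made with the QIAseq miRNA kit, which adds molecular identifiers. Per the submitters' processing notes the genome build was GRCm38. The aligner, the counter, the miRNA reference and the treatment of the molecular identifiers are not given in the sources used here, so the reads named below may be single molecules or may not.

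The authors deposited 1 table of 1452 features, 1184 miRNAs and 268 piRNAs. Its values are a scaled signal, called CPM per the file headers, but the columns sum to 819079 to 1220360 and so differ between libraries. Within each library 100% of the deposited signal values were whole multiples of the smallest (tolerance 0.001), so whole reads were recovered. The divisor behind the deposited values equals the read total times the TMM factor that edgeR gives for these reads, 0.819 to 0.882 in ME and 1.17 to 1.22 in L28BME. The authors' deposited log2 fold changes, signed fold changes (a score without values between -1 and 1) and p-values (raw, FDR and Bonferroni) compare L28BME with ME, and the tool is not named per the file headers. The deposited larger group mean equals that of the recovered reads. Column names give the group and a library number (001 to 006) but not the replicate number of the labels, so libraries are named by library number and were not paired.

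The list of tests, miRNA lists, alternatives and named miRNAs was set before the data were examined. It assumed CPM and named edgeR's quasi-likelihood test as the main one if the table also gave whole-number counts. The table gave scaled values only, and the column sums rule out plain CPM. The test planned for CPM was therefore run on the deposited signal, and edgeR on the recovered reads was kept as an alternative. miRNAs with a value of at least 5 in at least 3 libraries were kept (387). limma's trend test was run on log2(value + 1) over all 6 libraries with the group as the term, two-sided, and called at a Benjamini-Hochberg adjusted p under 0.05. A fold change on the log2(value + 1) scale understates the change of scarce miRNAs; folds in the text are ratios of group means. Of 16 miRNA lists 14 had at least 2 tested members and were tested with camera (preset correlation 0.01, and an estimated one as a check) and adjusted over the lists. fry, which tests whether a set moves on balance one way and does not compare it with other miRNAs, was run beside it: its adjusted p was 5.1e-08 for let-7 guides, 4.2e-06 for star strands, 5.1e-08 and 5.35e-07 for the 2 subclasses, 0.00945 for let-7 partners, 0.00359 for other GGAG-loop miRNAs and 0.0141 for the myeloid list (all downward), and 0.000127 for the Dlk1-Dio3 cluster and 0.0459 for the epithelial, liver, muscle and neural list (both upward). The other 5 lists did not pass fry. let-7 subclasses and library shares were compared by exact permutation. Intervals for reads pooled over a group are exact binomial (95%) and cover counting error only.

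Alternatives were other scalings (median-ratio, plain library size, total without let-7), filters, pseudocounts of 0.5 and 5, limma without trend or with sample weights, edgeR's quasi-likelihood test and DESeq2 on the recovered reads, other thresholds, the summed let-7 family and each library left out. On the recovered reads edgeR called 90 higher and 120 lower, and DESeq2 83 and 106. The piRNA features stayed out of the main test because the comparison concerns miRNAs. The miRNAs named in the text are each let-7 guide, the 10 largest rises and falls among called miRNAs without overlap and with a mean of at least 10, up to 4 most abundant members of each list, and the 5 most abundant of each group; others are named to complete a count or as marked. Loci and hairpin sequences are from GENCODE M21 (GRCm38).

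The code was tested on 10 simulated sets of negative binomial counts, drawn for both groups from the real ME means with the real dispersions. Library sizes were the real read totals times their TMM factors, so the simulated L28BME libraries held more reads than the real ones. In each set 200 miRNAs were changed by at most 4-fold, about as many up as down. A one-sided loss such as that of let-7 was not simulated, so the rates below do not cover its effect on scaling. limma called 90.4% of miRNAs with a 1.5-fold change (64.7 per set), 99.5% with 2-fold (63.9 per set) and 100% with 4-fold (63.5 per set), among 358 tested per set. Of its calls 1.79% were unchanged miRNAs. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and matplotlib 3.10.9.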

Results

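MicroRNAs were sequenced from mouse bone marrow GMLPs, a sorted progenitor population, after 3 days of culture with doxycycline (DOX), an antibiotic used to switch on inducible transgenes. The ME libraries (n = 3) came from mice with MLL-ENL, a fusion gene of leukaemia. The L28BME libraries (n = 3) came from mice that carried LIN28B as well, an RNA-binding protein of fetal cells that holds back the maturation of let-7 microRNAs. The ME libraries held 4778027 to 5528960 reads and the L28BME libraries 2745970 to 4332618. Outside the let-7 family the means differed by 1.10-fold, and an exact permutation test gave p = 0.7 (two-sided). Replicate libraries correlated at r = 0.996 to 0.998 on the log2 scale across miRNAs, which are not independent, and each pair differed by more than sampling noise (chi-square per degree of freedom of 13.6 to 72.9). No label says that the libraries came from separate mice or cultures. P-values of single miRNAs, of fry and of permuted libraries therefore measure the spread between these libraries, which may be technical. Those of camera compare a list with other miRNAs, and those permuted over members or hairpins compare miRNAs, so neither measures that spread.

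The comparison of L28BME with ME asked which miRNAs differ when LIN28B is present beside the fusion gene. The let-7 family, which restrains growth and fetal gene programmes, was almost lost from L28BME cells, with let-7c-5p as the exception. The let-7 guides, the strands that act on target mRNAs, made up 26.6% ± 0.701 of reads in ME and 3.25% ± 0.0454 in L28BME (SD, n = 3 each). Outside let-7 the changes were smaller. Higher in L28BME were miR-196a-5p, miR-342-3p, miR-130a-3p and 16 of 17 tested miRNAs on the fixed list of the imprinted Dlk1-Dio3 cluster. Lower were miR-30a-5p, miR-99a-5p and miR-146a-5p. The most abundant miRNAs of myeloid cells, miR-223-3p and miR-142a-3p, did not pass the test, though both were past the threshold and higher with plain library-size scaling (0.49 and 0.59 on the log2 scale).

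Among the guides let-7i-5p had the largest change, from 83444 ± 3202 in ME to 211 ± 8.90 in L28BME (SD, n = 3, deposited scaled values), a 396-fold lower mean (log2 change -8.62, SE 0.075, limma adjusted p = 9.26e-20). It is cut from Mirlet7i (GRCm38, chromosome 10, 122985640 to 122985724, minus strand), which overlaps an exon of the pseudogene D630033A02Rik. let-7d-5p fell 350-fold, miR-98-5p 346-fold, let-7j 273-fold, let-7g-5p 185-fold and let-7f-5p 132-fold. let-7a-5p fell 72.8-fold and let-7b-5p 67.5-fold. let-7e-5p, the least abundant of the tested guides in ME, fell 13.1-fold. let-7k had 9 reads over the ME libraries and 0 in L28BME and was under the filter. Members differ by few bases, so reads could be split between them in counting, and single members are uncertain to that extent. Without let-7c-5p the summed guides were 140-fold lower, and the exact permutation p was 0.1, the smallest that 3 against 3 libraries allow.

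let-7c-5p fell from 36345 ± 622 to 25365 ± 870 (SD, n = 3), a log2 change of -0.52 (SE 0.068, limma adjusted p = 2.16e-05), and was level with plain library-size scaling (-0.022, adjusted p = 0.757). It accounted for 11.5% ± 0.271 of let-7 guide reads in ME and 92.7% ± 0.0904 in L28BME, and for 3.06% ± 0.152 and 3.01% ± 0.0435 of all reads. In GRCm38 its sequence, TGAGGTAGTAGGTTGTATGGTT, is in 2 hairpins. Mirlet7c-1 lies on chromosome 16 (77599657 to 77599750, plus strand) in an intron of Mir99ahg. Mirlet7c-2 lies on chromosome 15 (85706603 to 85706697, plus strand) in an exon of Lncppara, 621 bases from Mirlet7b (85707319 to 85707403).

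**Figure D1:**
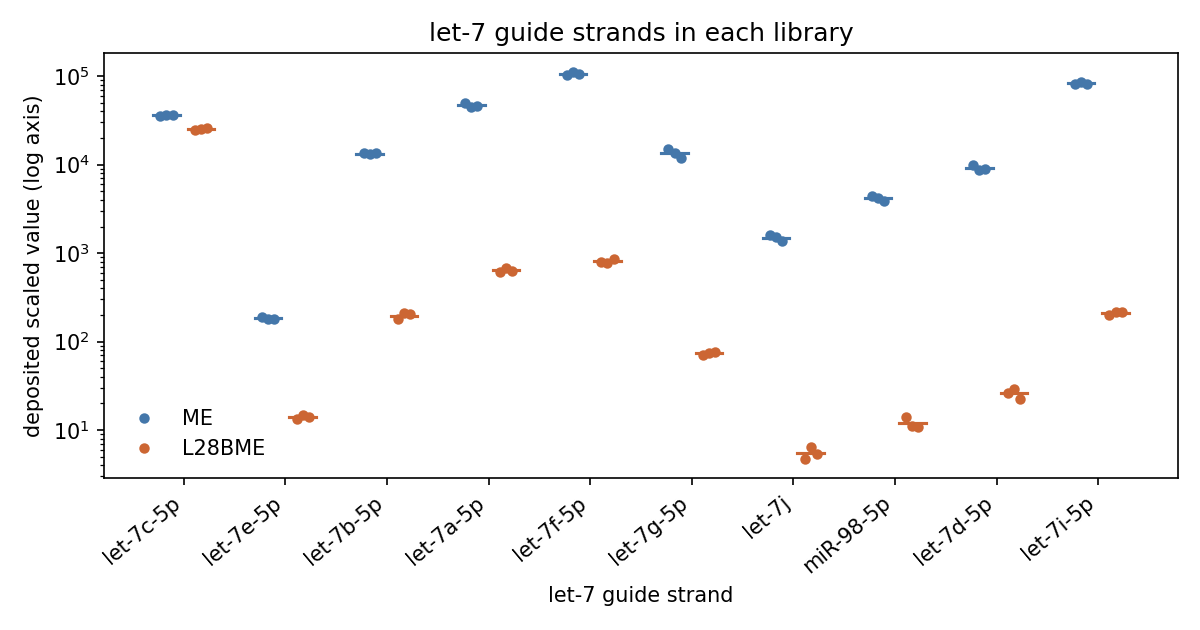
Deposited scaled values (log axis) of the 10 tested let-7 guide strands in each library; points are libraries, 3 ME and 3 L28BME, and short lines are group means. let-7c-5p sits at 36345 in ME and 25365 in L28BME (level with plain library-size scaling), while let-7i-5p goes from 83444 to 211.

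The let-7 guides were lower as a set, with all 10 tested members past the threshold (9 with plain library-size scaling) and a median log2 change of -7.28 (camera adjusted p = 2.24e-15, and adjusted p = 0.0301 with an estimated correlation). All 9 tested star strands, the opposite strands of the hairpins, were also lower (median -4.98, camera adjusted p = 1.78e-09, and adjusted p = 0.034 with an estimated correlation). Except let-7a-1-3p they passed the filter through ME alone, so that selection favoured a fall. Without the filter 9 of 10 listed star strands were lower (median -4.87, camera adjusted p = 2.90e-28). let-7i-3p fell from 162 ± 41.0 to 0.681 ± 0.241 and let-7d-3p from 189 ± 20.7 to 0.643 ± 0.363 (SD, n = 3). let-7f-1-3p had 1188 reads over the ME libraries and 1 in L28BME, a scaled ratio of 1157 (95% exact interval 207 to 45725, counting error alone). let-7a-1-3p fell least among the tested star strands, 3.89-fold, and its sequence is the same in the hairpins Mirlet7a-1 and Mirlet7c-2. The 5 guides whose precursors carry the LIN28 cold-shock-domain motif had a median change of -8.33 and the 3 without it -3.62. The difference was -4.71, and an exact permutation test over members gave a two-sided p = 0.0536. Several splits of the members share the largest possible difference of medians, so no smaller p could arise. The test could not pass and does not decide whether the subclasses differ. Both subclasses were lower as sets (camera adjusted p = 2.22e-09 and 0.000664), and for the second the call was lost at an adjusted p = 0.11 with an estimated correlation.

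The Dlk1-Dio3 cluster, imprinted miRNAs on distal chromosome 12 that are active in fetal tissue and blood stem cells, was higher in L28BME as a set (camera adjusted p = 6.83e-06, and 0.034 with an estimated correlation). Of 17 tested members of the fixed list 16 rose, with a median log2 change of 0.66, and miR-376c-3p had 0.27 (limma adjusted p = 0.236). miR-154-5p, at most 4.98 in ME, passed the filter through L28BME alone. miR-369-3p and miR-381-3p, averaging 4.45 and 4.98 in ME, also needed their L28BME values to pass it. Without the filter 19 of 40 listed members rose and 21 did not pass (median 0.55). Strands not on the list, among them miR-136-3p and miR-299a-3p, were not counted. miR-136-3p (Mir136, 109595327 to 109595388) rose by 1.30 on the log2 scale (limma adjusted p = 7.40e-06). miR-431-5p (Mir431, 109590447 to 109590537) went from 17.3 ± 0.821 to 42.3 ± 3.66, and miR-379-5p from 53.3 ± 5.36 to 84.5 ± 0.734 (SD, n = 3). miR-127-3p was 1.48-fold and miR-411-5p 1.68-fold higher. miR-541-5p was near the threshold (0.33, limma adjusted p = 0.0479) and lost its call in 10 alternatives. All scalings tried gave the same direction, though each of the 3 others shifts the bulk of miRNAs upward, whereas a set test on DESeq2 statistics did not pass (adjusted p = 0.187) with 13 members higher. The members are scarce, at scaled values under 100. miR-199a-3p, the 1 tested miRNA of a list for stromal and endothelial cells, rose beside them by 0.89 on the log2 scale (limma adjusted p = 1.09e-06).

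**Figure D2:**
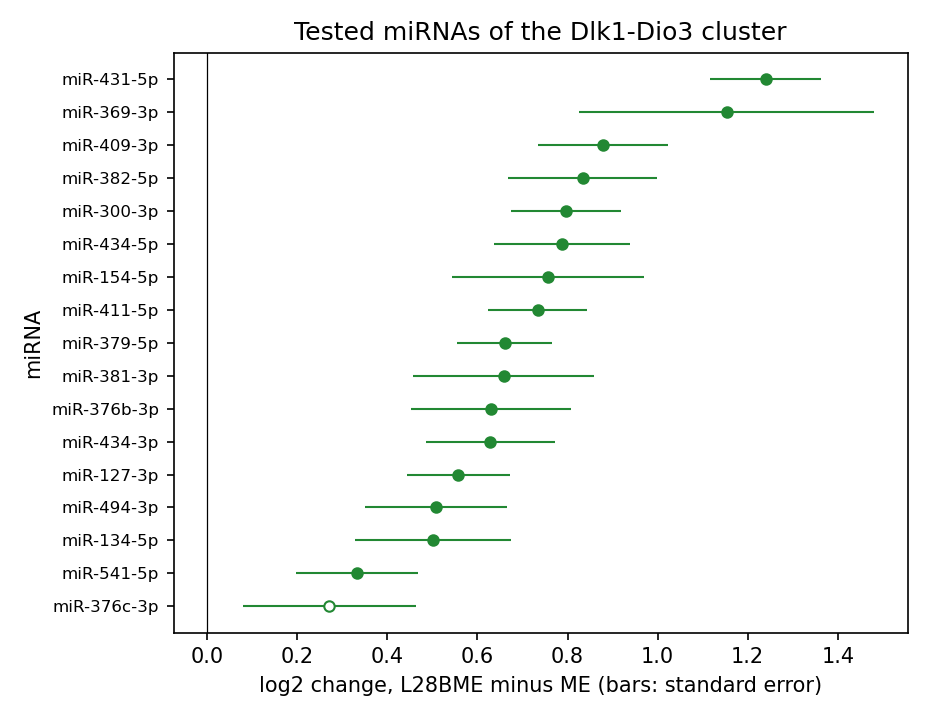
Log2 change (L28BME minus ME) with its standard error for the 17 tested miRNAs of the Dlk1-Dio3 cluster; filled points passed the adjusted p threshold of 0.05. Values run from 0.27 (miR-376c-3p, open point) to 1.24 (miR-431-5p).

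Among the miRNAs of the Hox loci, which lie beside the genes that MLL fusions activate, miR-196a-5p rose from 22.6 ± 3.67 to 67.5 ± 2.76 (log2 change 1.55, limma adjusted p = 1.45e-07), the largest rise on the log2(value + 1) scale; as a ratio of means, 2.99, it was under the 3.32 of the scarcer miR-582-5p. Its hairpins lie on chromosome 11 (Mir196a-1, 96265164 to 96265265) and in an intron of Hoxc5 on chromosome 15 (Mir196a-2, 102973350 to 102973434). The far more abundant miR-196b-5p, encoded at Hoxa9, was 14080 ± 952 in ME and 13840 ± 589 in L28BME (-0.024, not past the threshold; 0.47 and past it with plain library-size scaling). miR-10a-5p fell by 0.57 on the log2 scale (-0.071 and not past the threshold with plain library-size scaling). As a set the 3 tested members did not pass (camera adjusted p = 0.742; median -0.024, mean 0.32).

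Of 12 stem and progenitor miRNAs 4 rose and 3 fell (9 higher and 1 lower with plain library-size scaling). miR-130a-3p rose 2.54-fold, from 117 ± 18.5 to 297 ± 13.5, and miR-126a-3p, a miRNA of blood stem cells and endothelium, rose 1.39-fold. miR-126a-5p and miR-29b-3p rose as well (0.68 and 0.26 on the log2 scale), the latter without a call when any of 4 libraries was left out. miR-146b-5p fell from 12607 ± 315 to 6773 ± 83.4 (SD, n = 3), and miR-193b-3p and miR-181d-5p fell by 0.67 and 0.41 on the log2 scale (-0.20 and 0.082 with plain library-size scaling, neither past the threshold). The set did not pass (camera adjusted p = 0.742); its median was -0.12 (0.38 with plain library-size scaling), its mean 0.027 and the direction of the test upward.

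Of 12 myeloid differentiation miRNAs 6 were lower and 0 higher, while the set did not pass (camera adjusted p = 0.251). Its median log2 change was -0.18, and 0.32 with plain library-size scaling, where 7 were higher and 1 lower. miR-146a-5p, a brake on inflammatory signalling, fell from 9669 ± 394 to 5138 ± 133 (log2 change -0.91, limma adjusted p = 8.61e-08). miR-155-5p fell by 0.54 and miR-21a-5p by 0.49 on the log2 scale, calls that plain library-size scaling did not keep (-0.043 and 0.0072). miR-22-3p, miR-34a-5p and miR-223-5p were the other members past the threshold. With plain library-size scaling the first 2 were not past it (0.088 and 0.096) and miR-223-5p was past it in the other direction (0.30, limma adjusted p = 0.00260). miR-223-3p was 81003 ± 10646 in ME and 80283 ± 6629 in L28BME (SD, n = 3).

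Among lymphoid miRNAs miR-342-3p, from an intron of Evl (chromosome 12, 108658620 to 108658718), rose 2.58-fold, from 383 ± 18.1 to 988 ± 31.1 (SD, n = 3). miR-155-5p was the member that fell, and miR-181a-5p, miR-181b-5p and miR-150-5p did not pass. The set did not pass (camera adjusted p = 0.916; median -0.17, and 0.33 with plain library-size scaling, where 4 of 5 were higher; mean 0.064). The partners cut from the same primary transcripts as let-7 members went apart: miR-99a-5p fell 2.07-fold and miR-125b-5p 1.69-fold, while miR-99b-5p rose 1.42-fold and miR-125a-5p did not pass (camera adjusted p = 0.525; median -0.43, 0.068 with plain library-size scaling). miR-107-3p, reported to hold the LIN28 motif in its loop, fell 1.69-fold, and miR-200c-3p from the same list did not pass (camera adjusted p = 0.323; median -0.48, 0.016 with plain library-size scaling).

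In the growth-promoting miR-17~92 and paralogue clusters 4 of 13 members rose (miR-18a-5p, miR-18b-5p, miR-19a-3p and miR-19b-3p, log2 changes 0.32 to 0.53; 2 of 13 by limma without trend), miR-92a-3p fell by 0.53 on the log2 scale (-0.030 with plain library-size scaling, not past the threshold), and 8 did not pass. The set did not pass (camera adjusted p = 0.323), though it did with plain library-size scaling (adjusted p = 0.0469), where 12 members were higher and 0 lower. In the miR-15/16 family 1 of 6 members rose, the scarce miR-497a-5p, and 0 rose with DESeq2, without a filter, or without ME library 002 or L28BME library 005. miR-16-5p, the most abundant miRNA in both groups, was 155686 ± 3289 in ME and 144701 ± 12645 in L28BME (not past the threshold). The set gave a camera adjusted p = 0.742, and its median of 0.013 became 0.51 with plain library-size scaling, where 6 of 6 were higher. Adjusted over the list alone, every list kept its counts except the myeloid list, with 5 lower, and the miR-15/16 family, with 0 higher.

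Markers of other cells were few. The 4 listed erythroid miRNAs were under the filter, and miR-451a averaged 0.379 in ME and 1.41 in L28BME. Of the stromal and endothelial list miR-199a-3p alone was tested and rose from 190 ± 10.8 to 353 ± 5.18 (SD, n = 3), while the 4 other listed members stayed under the filter. Of these miR-199a-5p had 8 reads in ME and 1 in L28BME, while the more abundant miR-199b-5p, whose hairpin holds the sequence of miR-199a-3p as well, rose from 6.65 to 18.5; miR-10b-5p averaged 2.90 and 1.73, whereas miR-143-3p averaged 1.75 and 2.59. Among 6 tested miRNAs of epithelium, liver, muscle and nerve miR-200a-3p rose 1.31-fold, and 3 of 6 were higher without ME library 002, with median-ratio factors or with the total without let-7. That set did not pass camera (adjusted p = 0.323) but passed fry (upward, adjusted p = 0.0459), and with plain library-size scaling 5 of 6 were higher (median 0.68).

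In all, limma tested 387 miRNAs, of which 93 were higher and 124 lower in L28BME at an adjusted p under 0.05. Of the lower ones 19 were let-7 guide or star strands and 105 lay outside the family. On the log2(value + 1) scale a change of at least 1 was seen for 14 of the higher miRNAs and for 7 of the lower ones outside let-7. Among called miRNAs with a mean of at least 10 the further large rises were miR-3062-5p, miR-199b-5p, miR-5121, miR-582-3p and miR-210-3p, a miRNA induced by hypoxia. With miR-136-3p of the Dlk1-Dio3 cluster, named above, their log2 changes ran from 1.14 to 1.44. The further falls were miR-879-3p and miR-146b-3p (-1.13 and -1.12). Of the scarcer ones miR-7676-3p had the largest fall outside let-7 (9.92 to 1.85, log2 change -1.94, limma adjusted p = 7.40e-06), and miR-582-5p rose from 3.36 to 11.2. miR-30a-5p, named after its value was seen, fell from 610 ± 33.0 to 289 ± 12.8 (SD, n = 3). The 3 ME and 3 L28BME values did not overlap for 238 miRNAs (61.5%, against 10% by chance). In the authors' deposited table an FDR p under 0.05 was given to 217 features, 96 higher and 121 lower, and the 179 tested miRNAs among them were all called here in the same direction. The split depended on scaling: plain library size raised the median change of all tested miRNAs from -0.014 to 0.49 and gave 255 higher and 33 lower (88.5% higher, against 42.9%), and the total without let-7 gave a median of 0.093 with 136 higher and 97 lower (58.4%). Changes outside let-7 are therefore relative to the bulk of miRNAs, and a fall of up to about that shift depends on the scaling for its direction. No scaling used here gives amounts per cell, so rises and larger falls outside let-7 are not fixed in absolute terms either.

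**Figure D3:**
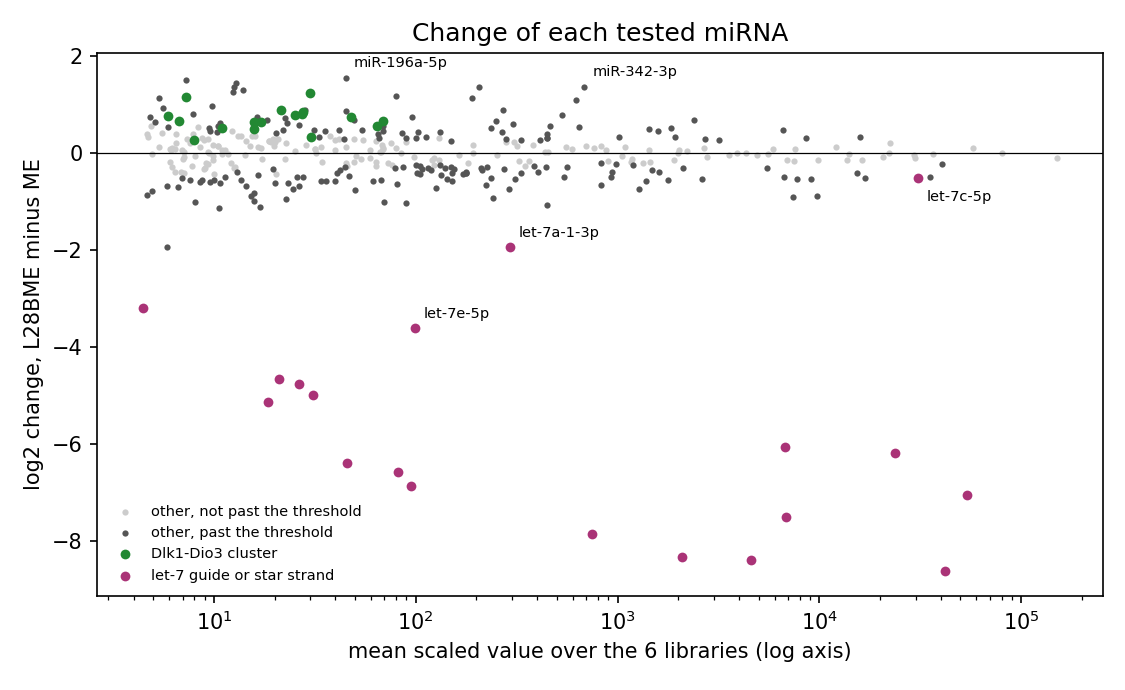
Log2 change (L28BME minus ME) of the 387 tested miRNAs against their mean scaled value over the 6 libraries (log axis). Colours mark let-7 strands, members of the fixed Dlk1-Dio3 list and other miRNAs past or not past the adjusted p threshold of 0.05. Most let-7 strands lie far below the rest, with let-7c-5p at -0.52 (-0.022 with plain library-size scaling), and all other miRNAs lie between -1.94 and 1.55.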

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

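The test of the piRNA features was chosen after the main results were seen. These features lie outside the comparison of miRNAs and were looked at because the deposited table holds them. Of 39 tested together with the miRNAs, 8 were higher and 7 lower in L28BME by limma at an adjusted p under 0.05. piR-62566 had the largest change, from 1.84 ± 0.417 in ME to 8.63 ± 1.93 in L28BME (SD, n = 3; log2 change 1.75, limma adjusted p = 1.86e-05). The more abundant piR-3166 went from 207 ± 26.3 to 317 ± 20.9 (0.62, limma adjusted p = 0.000218). At the other end piR-68030 and piR-64065 fell by 0.68 and 0.66 on the log2 scale. Together piRNA features took 0.337% ± 0.0225 of reads in ME and 0.476% ± 0.0384 in L28BME (SD, n = 3), and an exact permutation test gave 0.1, the smallest p that 3 against 3 libraries allow. Of reads outside let-7 they took 0.460% ± 0.0351 and 0.492% ± 0.0396 (exact permutation p = 0.4), so the loss of let-7 reads enters the first comparison. No explanation was tested.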

How the results depend on the processing

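The thinned-read and piRNA alternatives were chosen after the data were seen; the others were planned. No paired analysis was possible because the table's columns carry no replicate numbers, so the planned replicate block was not run. The let-7 guides kept their direction and call in every alternative (medians -7.33 to -6.78, and -3.53 as 1 summed value). The subclass difference stayed between -4.84 and -4.62, and its test could not pass in any alternative. With plain library size 255 miRNAs were higher and 33 lower, and 126 of the 217 calls remained; the let-7 share of ME reads enters that scaling. There the sign turned for miR-125a-5p (0.39), miR-93-5p (0.46), miR-25-3p (0.38), miR-20a-5p (0.46), miR-196b-5p (0.47), miR-200c-3p (0.29, past the threshold in neither fit), miR-223-3p (0.49), miR-21a-5p (0.0072), miR-29a-3p (0.41), miR-181a-5p (0.36), miR-181b-5p (0.29), miR-16-5p (0.39), miR-322-5p (0.48), miR-15b-5p (0.45) and miR-191-5p (0.27), and let-7c-5p, miR-92a-3p, miR-10a-5p and miR-155-5p lost their calls. The medians of let-7 partners (0.068), other GGAG-loop miRNAs (0.016), Hox-cluster (0.47), myeloid (0.32), stem and progenitor (0.38) and lymphoid miRNAs (0.33) turned there without a call. Small values past the threshold in neither fit also turned: miR-196b-5p with the Hox list (0.00095), miR-223-3p (0.017) and miR-322-5p (0.010) with median-ratio factors; the same with DESeq2 (0.00016, 0.016 and 0.0066); and with the total without let-7 (0.073, 0.089 and 0.083), as did miR-93-5p (0.063), miR-20a-5p (0.055), miR-29a-3p (0.0067) and miR-15b-5p (0.048). With sample weights miR-15a-5p (-0.044) and the miR-17~92 (-0.0071) and miR-15/16 lists (-0.056) turned, the last also with a minimum of 50 (-0.032) and thinned reads (-0.0069). A minimum of 50 left 215 miRNAs to test, hence 49 higher and 82 lower. Leaving out each library in turn gave 66 to 93 higher, 94 to 123 lower and 4 to 5 lists; without an ME library a single let-7 star strand passed the filter, so that list had no test. Ranges over the left-out libraries crossed 0 without a call on the turned side for miR-93-5p (-0.13 to 0.042), miR-20a-5p (-0.17 to 0.055) and miR-15b-5p (-0.15 to 0.074), turned without ME library 001; miR-223-3p (-0.11 to 0.081) and miR-322-5p (-0.13 to 0.044), without ME library 001 or 002 or L28BME library 004; miR-196b-5p with the Hox list (-0.058 to 0.031), without ME library 002 or L28BME library 005; miR-15a-5p (-0.096 to 0.12) and the miR-15/16 list (-0.12 to 0.099), without ME library 003; and the miR-17~92 list (-0.013 to 0.057), without ME library 003 or L28BME library 006. Among named miRNAs 1201 values kept sign and call, 41 turned (27 of them past the threshold in neither fit), 25 lost and 19 gained a call. These counts and those of the lists include TMM factors recomputed from the reads. That alternative repeats the main fit, so its values were kept by construction. miR-541-5p lost its call in 10 alternatives (adjusted p 0.0545 to 0.218), among them the fits without ME library 001 or 003 or L28BME library 004 or 006. miR-29b-3p lost its call without ME library 002 or 003 or L28BME library 005 or 006 (adjusted p 0.0582 to 0.116), and miR-191-5p without ME library 001 or L28BME library 004 or 006 (0.0550 to 0.0744). Calls gained by leaving out 1 library were miR-25-3p and miR-20a-5p without ME library 003, miR-141-3p without ME library 002, miR-142a-5p without ME library 002 or L28BME library 004, and miR-181b-5p without ME library 001 or L28BME library 004 (0.0259 to 0.0438). Of the single lists 236 values stayed and 18 turned, none past the threshold, while the Dlk1-Dio3 cluster lost its call with DESeq2 (median 0.77; the cause was not tested), and 2 gained one (miR-17~92 with plain library size, median 0.51; myeloid without a filter, -0.18). Depth limits the star strands in L28BME, several of which rest on 1 read.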

Other observations

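Apart from the counts over splits of the libraries, the tests in this part were chosen after the result was seen. Across the 87 hairpins outside let-7 with both strands tested, the strands moved together (Pearson r = 0.816, Spearman rho = 0.799, each with a permutation p of 1e-04, the smallest that the permutations can give; hairpins are not independent). Both strands passed in 32 hairpins, and in all 32 they had the same direction. miR-30a-5p and miR-30a-3p fell by 1.07 and 1.01 on the log2 scale, miR-146a-5p and miR-146a-3p by 0.91 and 0.71, and miR-574-3p and miR-574-5p by 0.96 and 0.84. miR-221 and miR-222, neighbours on the X chromosome that restrain the cell-cycle inhibitor p27, fell on both strands as well (miR-221-3p by 0.53, miR-222-3p by 0.67). miR-342, miR-582, miR-301a and miR-126a rose on both strands, with miR-342-5p at 0.97 and miR-301a-3p at 1.09. These were picked after their values were seen, and plain library size shifts the median upward by 0.50, which leaves miR-221-3p at -0.037, miR-222-3p at -0.17, miR-222-5p at 0.084, miR-146a-3p at -0.28 and miR-574-5p at -0.37, none past the threshold, and miR-221-5p past it at -0.43.

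let-7c-5p fell far less than the other let-7 guides. Reads of other members assigned to it do not account for this: had all its ME reads come from the least reduced member, such reads would make up at most 12.5% of its reads in an L28BME library. Scaling does not either, since the log2 ratio of let-7c-5p to the other guides within a library, which no scaling can move, differed by 6.61 ± 0.025 (SE) between the groups. A candidate explanation is that the Mirlet7c-2 precursor escapes LIN28B, as has been reported for it: the star strand it shares with Mirlet7a-1, let-7a-1-3p, kept 3.68 more on the log2 scale than the least reduced of the tested star strands it does not share, beyond counting error (let-7e-3p, with 6 reads and 1, was too scarce to test), while let-7c-1-3p went from 115 reads to 1. The GGAG motif does not settle the cause, being missing after the guide in 3 of 12 hairpins, of which Mirlet7b and Mir98 lost their guides, and a change in transcription was not tested.

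let-7a-5p and let-7b-5p, 1 base from let-7c-5p, kept 1.37% and 1.48% of their ME level, against 0.253% to 0.755% for let-7d, let-7f, let-7g, let-7i and miR-98. Some of what was left may be let-7c-5p reads with 1 error. Across 8 guides the bases that separate a guide from let-7c-5p were set against the scaled level left, to which such reads would add. Spearman rho was -0.16 (exact p = 0.705) and Pearson r was -0.22 (exact p = 0.596). Without the 2 members farthest from the median distance r was -0.41, though the second of them was picked among ties. With the share left rho was -0.78 (exact p = 0.0310; Pearson r = -0.58, exact p = 0.133), which restates how the pattern was found and does not test it. let-7e-5p, 2 bases away, kept 7.65%, and the let-7b star strand did not fall further than its guide beyond counting error (log2 difference 0.23), so this stays open, and the folds of let-7a-5p and let-7b-5p would then be lower limits.

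The rise of the Dlk1-Dio3 cluster was set against scaling, depth and a larger share of stem-like cells. Within a library no scaling factor enters. There the cluster's log2 gap to 163 other miRNAs of its abundance range differed by 0.76 ± 0.073 (SE) between the groups. Scaling therefore does not account for the rise. After thinning each library to 2654861 reads outside let-7 the cluster's median change was 0.72 ± 0.083. Thinning leaves the expected share of each miRNA unchanged and could hardly have removed the rise, so it does not decide on depth. Reads outside let-7 ran from 2654861 to 4192216 in L28BME and from 3465097 to 4071269 in ME. A larger share of stem-like cells in the L28BME cultures could raise the cluster and cannot be told apart: the stem and progenitor list gave a camera adjusted p = 0.742, with members in both directions. Other cell types were not weighed: of the stromal and endothelial list 1 member was tested, miR-199a-3p, which rose, and without a filter on low values 3 of 4 erythroid miRNAs were higher. An effect of LIN28B on the cluster was not tested and stays open as a hypothesis.

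The 6 libraries can be split into 3 and 3 in 10 ways, so the share of splits with a result as large cannot fall under 0.1. For called miRNAs it was 1 of 10, with 217 in the real split and at most 0 in any other. For lists past the threshold it was 2 of 10, with 5 in the real split and 2 to 5 in every other. Each other split sets 2 libraries of a group against 1 and so keeps part of the let-7 difference, which bears on the count of lists. It also puts the group differences into the spread within each side, which works against calls of single miRNAs. Neither count can therefore weigh chance.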
